A study of Homo sapiens with 6 samples.

How the data were processed

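RNA from human lung microvascular endothelial cells (HMVEC-L), primary cells that line the small vessels of the lung, was profiled by RNA-seq. Per the labels' protocols, cells were transfected with a Silencer Select siRNA against CFTR (the siCFTR group) or a negative control siRNA (the siNegControl group), each at 40 nM, and libraries were made with a low-input kit that does not mark strand. There were 3 libraries per group and 6 in all. Nothing in the labels says that replicates came from separate cultures or donors, so p-values measure only the spread between these libraries, which may be technical.

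The deposited file of each library pairs a gene symbol with 1 value, for 27971 symbols. The submitters' processing notes name STAR, Salmon, DESeq2 and the hg19 build, without versions, roles or order. The files are named as counts, but the deposited values are not counts. They carry 1 decimal, between 91.5% and 92.1% of the nonzero values in a library are fractional, and they sum to between 1677480.8 and 2042408.5 per library. Between siNegControl 1 and 3, the variance of values from 1 to 10 was on average 0.209 times their mean for transcripts of 500 to 1500 nt and 0.0545 times for transcripts of 6000 to 20000 nt, where whole reads would give at least 1. The deposited values were therefore treated as a length-normalised abundance in a unit that is not given in the sources used here. Depth is unknown, the totals above are not read depths, and no counting interval can be given.

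A count-based test had been fixed before the data were examined. Because the unit does not allow it, limma (version 3.58.1, R 4.3.3) with an intensity trend and robust variance moderation was run on log2(value + 1), where the value is scaled to an effective library total of 1000000 (ppm). Scaling used the library total times a trimmed mean of log ratios (30% trimmed from the ratios and 5% from the mean levels at each end), written without the precision weights that need counts. Genes with at least 1 ppm in at least 3 libraries were tested, which left 12339. All fold changes are on the log2(value + 1) scale, which understates the change of low genes. P-values are two-sided with Benjamini-Hochberg adjustment, and a gene passed at an adjusted p under 0.05. On simulated data with 12401 genes for siCFTR against siNegControl, 61.0% of 100 genes changed by 1 log2 unit and 96.0% of 100 changed by 2 were recovered, with 6 false calls.

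The genes named were set by a rule written before the data were examined. It takes CFTR, TRPV4 and PIEZO1. It then takes up to 12 genes per direction with the largest log2 fold change among those that passed, with a mean of at least 5 ppm and groups that do not overlap. CFTR and symbols of clones or unnamed loci were left out of that part, and XIST and Y-linked genes of every part. One gene that the rule takes is not reported here. The rule also takes up to 4 members of each fixed list in order of p.

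In the same way 35 gene lists were fixed. The 30 with at least 5 tested members were tested with camera (limma) at a preset inter-gene correlation of 0.01, with adjustment over the 30 lists. An estimated correlation, and fry, which tests a list's genes without comparing them with others, were alternatives. Fry called, with an adjusted p of 0.0299 for each, the unfolded protein response list and the TGF-beta list; with an estimated correlation none of the 30 was called. Members past the threshold were counted after adjustment over all tested genes and adjusted over the list alone.

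Alternatives changed the scaling, the filter, the pseudocount, a fold minimum, the replicate number as a block and each library left out. A further setting, added after the data were seen, removed from each library a smooth trend (natural splines with 5 degrees of freedom) of its deviation on transcript length and GC content. Length, GC content and 3′ UTR sequence came from 1 transcript per symbol of GENCODE release 29, which is built on another assembly than the files, so no coordinates are given. It matched 98.1% of tested genes. A scan of heptamers in 3′ UTRs was run with Python 3.11.15 (numpy 2.4.6, scipy 1.17.1) and recovered 1 heptamer effect planted in shuffled genes.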

Results

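The series asks how lowering CFTR, the chloride channel mutated in cystic fibrosis, alters gene expression and lipid metabolism in lung microvascular endothelium, and its title names the mechanosensitive channels TRPV4 and PIEZO1 and the endothelial barrier. It holds 3 libraries of HMVEC-L cells given a CFTR siRNA and 3 given a negative control siRNA. Between 16312 and 16967 symbols had a value above 0 in a library. Values are abundances scaled to ppm, of unknown depth, and are given as mean ± SD with n = 3 per group.

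CFTR itself was listed at 0 in all 6 libraries, controls included. The files hold 1 decimal, so a level that rounds to 0 cannot be told from none, and the values offer no check of the knockdown. Every direction below therefore rests on the library labels alone.

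Between siCFTR and siNegControl, 39 of 12339 tested genes passed, 14 higher and 25 lower in siCFTR. The largest fall was in KDR, the main VEGF receptor of endothelial cells, from 109 ± 20.1 to 16.2 ± 6.15 ppm, a log2 fold change of −2.73 (SE 0.28, limma adjusted p = 0.0222). ANO2, a calcium-activated chloride channel, fell from 34.2 ± 1.15 to 9.85 ± 3.72 ppm, and CPOX, an enzyme of haem synthesis, from 13.8 ± 0.726 to 3.83 ± 0.138 ppm. The actin-binding protein LASP1 fell from 411 ± 25.9 to 142 ± 29.3 ppm and the death receptor FAS from 87.8 ± 6.41 to 29.9 ± 4.23 ppm. SLC7A11, the cystine transporter that feeds glutathione synthesis, fell from 48.1 ± 11.3 to 18.2 ± 1.93 ppm. The log2 fold changes were −1.53 (SE 0.17) for POFUT1, which fucosylates Notch receptors, −1.49 (SE 0.17) for UGGT1, the glycoprotein folding sensor of the endoplasmic reticulum, and −1.33 (SE 0.16) for OGA, which removes O-GlcNAc. TAF13, a subunit of the general transcription factor TFIID, fell by 1.26 on the log2 scale, and MICALL1, a protein of endocytic recycling, fell by 1.25. MIR1825 fell by 1.95, but its symbol lies inside POFUT1 in the RefSeq gene table (GRCh38), so its value is uncertain.

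HMGA2, a chromatin architectural protein, had the largest rise, from 36.5 ± 7.18 to 103 ± 5.40 ppm, a log2 fold change of 1.49 (SE 0.16, limma adjusted p = 0.0222). The axon guidance ligand SEMA3C rose from 5.33 ± 1.17 to 14.5 ± 0.121 ppm and the BMP antagonist GREM1 from 24.7 ± 2.95 to 56.7 ± 6.49 ppm. PDIA4, a disulfide isomerase of the endoplasmic reticulum, rose from 56.0 ± 2.20 to 112 ± 2.43 ppm. The other risers were MEDAG (log2 fold change 1.19, SE 0.15), the autophagy factor NRBF2 (1.05, SE 0.14), the methionine sulfoxide reductase MSRB3 (0.89, SE 0.13) and the noncoding RNA LINC00537 (0.89, SE 0.13). PSG4, with a log2 fold change of 1.35 (SE 0.14), belongs to a family of close paralogs, and H3F3A and H3F3AP4, each at 1.37 (SE 0.20), are near-identical copies, so these values are uncertain. Limma adjusted p-values of the 23 genes lay between 0.0138 and 0.0461.

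**Figure D1:**
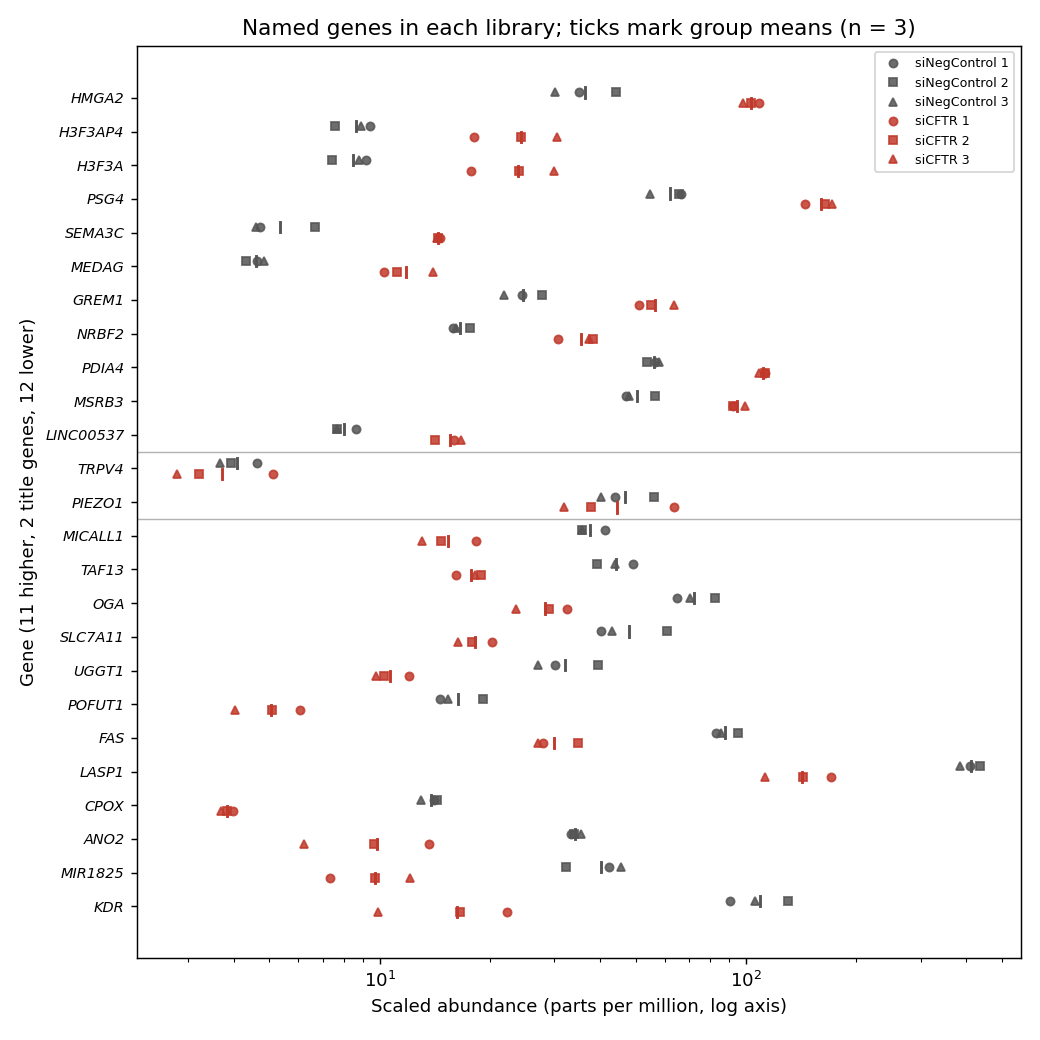
Scaled abundance in ppm (log axis) of the 11 named higher genes, TRPV4 and PIEZO1, and the 12 named lower genes. Each point is 1 library, grey for siNegControl and red for siCFTR, and vertical ticks are group means (n = 3). The groups are apart for the 23 called genes, as for KDR at means of 109 and 16.2 ppm, and overlap for TRPV4 and PIEZO1.

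The count depended on single libraries. No gene passed without siNegControl 1, 2 or 3 or without siCFTR 2, where 854, 1029, 808 and 770 genes had an unadjusted p under 0.05 (1410 with all 6 libraries), while 151 passed without siCFTR 1, 127 without siCFTR 3 and 329 (150 higher and 179 lower) once each library's trend on transcript length and GC content was removed. The heptamer GATTCTG, picked from these same fold changes, was in the 3′ UTR of 9 of the 11 named lower genes with a searched 3′ UTR, 1 of 9 such named higher genes and 14.8% of all searched genes; KDR, which fell, and PDIA4, which rose, carried it in the coding sequence. GACGTA, picked in the same way, was in 3 of those 9 higher genes and in 513 of the 11242 searched genes. Testing against a fold of at least 1.5 gave 0 genes by limma, with 96 at an unadjusted p under 0.05.

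Neither TRPV4 nor PIEZO1, calcium-permeable channels opened by mechanical force, passed. TRPV4 was at 4.07 ± 0.495 ppm in siNegControl and 3.71 ± 1.23 ppm in siCFTR, a log2 fold change of −0.13 (SE 0.20, limma adjusted p = 0.785). PIEZO1 was at 46.7 ± 8.30 and 44.5 ± 16.9 ppm, a log2 fold change of −0.12 (SE 0.26, limma adjusted p = 0.863). In both cases siCFTR 1 lay above every control (5.10 ppm for TRPV4 and 63.7 ppm for PIEZO1) and siCFTR 2 and 3 lay below every control. The PIEZO1 value changed sign, to 0.12 once the length and GC trend was removed, 0.01 without siNegControl 2 and 0.09 without siCFTR 3, and the TRPV4 value to 0.01 without siCFTR 3. Among 19 tested mechanosensitive channels none passed, over all genes or adjusted over the list alone (median log2 fold change −0.15, camera adjusted p = 0.247); the member with the smallest p was TMEM63A at −0.46 (SE 0.21; −0.68 to −0.27 with 1 library left out). Without siCFTR 1 the list of mechanosensitive channels was called lower (median −0.34, camera adjusted p = 0.0227), without siCFTR 3 its adjusted p was 0.957, and once the length and GC trend was removed its median was −0.04 (camera adjusted p = 0.751). Its median was 0.06, −0.16 and −0.41 in siCFTR 1 to 3. Of 31 calcium signalling genes none passed either (median −0.04, camera adjusted p = 0.981).

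Chloride transport genes and CFTR partners ranked lower in siCFTR (34 tested, median −0.17, camera adjusted p = 0.0315 at the preset and 0.982 with an estimated correlation), with 1 member past the threshold over all genes and 1 adjusted over the list alone, ANO2. The NKCC1 cotransporter gene SLC12A2 was at −0.75 (SE 0.24), and GOPC, which encodes a Golgi protein that binds CFTR, was at 0.44 (SE 0.14). The list's adjusted p was 0.331 (median −0.07) once the length and GC trend was removed, 0.228 without siNegControl 2 and 0.430 without siCFTR 3. It moved with the length gradient given below, from a median of 0.06 in siCFTR 1 to −0.42 in siCFTR 3.

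Of the lipid lists, 2 ranked lower in siCFTR. Cholesterol synthesis genes (23 tested) had a median log2 fold change of −0.26 (camera adjusted p = 8.12e-05 at the preset and 0.386 with an estimated correlation), and the list median lay below that of every control in all 3 siCFTR libraries. None passed over all genes and 2 did adjusted over the list alone, HMGCS1, which makes HMG-CoA, from 192 to 92.5 ppm (log2 fold change −1.07, SE 0.18), and TM7SF2, a sterol reductase (−0.70, SE 0.17). The sterol sensor gene INSIG1 was at −0.46 (SE 0.15). Fatty acid synthesis and desaturation genes (18 tested) had a median of −0.25 (camera adjusted p = 0.00216 at the preset and 0.934 with an estimated correlation), with none past either threshold. The list median was −0.04 in siCFTR 1, against −0.03 in the lowest control, −0.27 in siCFTR 2 and −0.38 in siCFTR 3, and the ribosomal protein median was also farthest from the controls in siCFTR 3 (1.05). The members with the smallest p included ACLY, which makes cytosolic acetyl-CoA, at −0.92 (SE 0.28) and the desaturase FADS2 at −0.75 (SE 0.24). Once the length and GC trend was removed, the cholesterol synthesis median was −0.25 (camera adjusted p = 5.54e-06 at the preset, 0.446 with an estimated correlation). The fatty acid synthesis median was then −0.23 (camera adjusted p = 0.0029 at the preset, 0.879 with an estimated correlation).

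The other lipid lists did not pass. Among 28 genes of lipid uptake, transport and storage (camera adjusted p = 0.878), GPIHBP1, which anchors lipoprotein lipase to capillary endothelium, fell from 6.73 to 2.47 ppm (log2 fold change −1.17, SE 0.16, limma adjusted p = 0.0386) and was the 1 member past the threshold, over all genes and adjusted over the list alone. Glycerophospholipid and triglyceride genes (36 tested, median −0.08, camera adjusted p = 0.190) had none past the threshold over all genes and 2 adjusted over the list alone, the acyltransferase AGPAT2 at 1.15 (SE 0.23) and the lipin LPIN3 at −0.64 (SE 0.13). In the eicosanoid and phospholipase A2 list (17 tested, median 0.02, camera adjusted p = 0.986), PLA2G15 at −0.68 (SE 0.13) was the 1 member past the threshold adjusted over the list alone. Fatty acid oxidation (21 tested, median 0.02, camera adjusted p = 0.981) and sphingolipid metabolism (30 tested, median 0.02, camera adjusted p = 0.979) had none by either count.

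No gene of the endothelial junction and barrier list passed, over all genes or adjusted over the list alone (39 tested, median −0.12, camera adjusted p = 0.420). The list median was 0.12, −0.09 and −0.25 in siCFTR 1 to 3. Once the length and GC trend was removed the median log2 fold change was −0.03 (camera adjusted p = 0.797). JAM3, a junctional adhesion molecule, was at −0.46 (SE 0.20; −0.64 to −0.25 with 1 library left out) and the junction claudin CLDN11 at 0.29 (SE 0.14). None passed by either count among 31 actomyosin contractility genes (median 0.01, camera adjusted p = 0.979) and 27 endothelial activation and NF-kB targets (median 0.02, camera adjusted p = 0.979). Nor did any of 36 interferon response genes (median −0.05, camera adjusted p = 0.493). Without siNegControl 2 the interferon response list was called lower (median −0.24, camera adjusted p = 3.74e-05). The interferon median was 0.19, −0.45 and 0.24 in siNegControl 1 to 3 and 0.02, 0.11 and −0.35 in siCFTR 1 to 3. Extracellular matrix genes (31 tested, median −0.13, camera adjusted p = 0.227) had 1 member past the threshold adjusted over the list alone, the stromelysin MMP10 at 0.91 (SE 0.18). Without siCFTR 1 the extracellular matrix list was called lower (median −0.36, camera adjusted p = 0.00186), without siCFTR 3 its adjusted p was 0.834, and once the length and GC trend was removed its median was −0.05 (camera adjusted p = 0.723). Its median was 0.32, −0.19 and −0.47 in siCFTR 1 to 3.

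Among markers of cell type, pan-endothelial genes ranked lower in siCFTR (18 tested, median −0.14, camera adjusted p = 0.0361 at the preset and 0.934 with an estimated correlation), with KDR the 1 member past the threshold over all genes and adjusted over the list alone. The next by p was SOX18 at −0.73 (SE 0.20). That list's adjusted p was 0.286 (median −0.02) once the length and GC trend was removed, 0.0554 without siNegControl 1, 0.103 without siNegControl 3 and 0.389 without siCFTR 3, the library in which its median was lowest (−0.42). Lymphatic (5 tested, median 0.03, camera adjusted p = 0.979) and blood vascular markers (11 tested, median −0.14, camera adjusted p = 0.609) had none by either count. Of the markers of fibroblasts, epithelial cells and leukocytes 4 each reached the filter, and of smooth muscle cells and pericytes 2. Those 4 lists were too short to test, their medians were 0.32, 0.11, 0.05 and 0.11 in that order, and no member passed by either count.

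TGF-beta and endothelial-mesenchymal transition genes ranked higher in siCFTR (24 tested, median 0.28, camera adjusted p = 0.00697 at the preset and 0.386 with an estimated correlation), with the list median above that of every control in all 3 siCFTR libraries. None passed over all genes, and 6 did adjusted over the list alone, 5 higher and 1 lower. They included the ligand gene TGFB2, from 16.6 to 31.2 ppm (log2 fold change 0.86, SE 0.15), TGFBI at 0.51 (SE 0.11), the transcription factor gene SNAI2 at 0.77 (SE 0.19) and, lower, the receptor gene TGFBR1 at −0.73 (SE 0.17). The list's adjusted p was 0.0729 without siCFTR 1. With the length and GC trend removed the median was 0.26 (camera adjusted p = 0.0203 at the preset, 0.446 with an estimated correlation). The list shares FAP, POSTN and COL1A2 with the 4 tested fibroblast markers, whose median was 0.51, 0.25 and 0.09 in siCFTR 1 to 3 and between −0.13 and 0.29 in the controls.

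The unfolded protein response list also ranked higher (29 tested, median 0.23, camera adjusted p = 0.0330 at the preset and 0.394 with an estimated correlation), with PDIA4 the 1 member past the threshold over all genes and adjusted over the list alone. Once the length and GC trend was removed, the median was 0.13 (camera adjusted p = 0.0206 at the preset, 0.446 with an estimated correlation). The chaperone gene HSPA5, which encodes BiP, was at 0.36 (SE 0.13), and WARS at −0.51 (SE 0.15). Its adjusted p was 0.0709 without siNegControl 3, 0.0829 without siCFTR 1 and 0.0961 without siCFTR 2. Heat shock genes had none by either count (16 tested, median −0.01, camera adjusted p = 0.979).

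Lists of flow and vessel patterning held members on both sides. In the shear-responsive KLF2 and KLF4 list (16 tested, median −0.07, camera adjusted p = 0.645) none passed over all genes and 7 did adjusted over the list alone, 3 higher and 4 lower. Thrombomodulin (THBD) was at 0.68 (SE 0.11) and KLF4 at 0.78 (SE 0.15), while the antioxidant enzyme genes TXNRD1 and HMOX1 were at −1.13 (SE 0.20) and −0.62 (SE 0.13). Notch and arterial genes (16 tested, median −0.09, camera adjusted p = 0.423) had none over all genes and 4 adjusted over the list alone, namely the ligand genes DLL4 at −0.92 (SE 0.20), JAG2 at −0.64 (SE 0.17) and JAG1 at 0.76 (SE 0.20), and the netrin receptor gene UNC5B at −0.83 (SE 0.18). Once the length and GC trend was removed the Notch and arterial median was −0.003. YAP and TEAD targets (21 tested, median −0.01, camera adjusted p = 0.986) had none over all genes and 3 adjusted over the list alone, AXL at −0.89 (SE 0.14), FJX1 at 0.66 (SE 0.14) and TGFB2.

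The p53 and apoptosis list (24 tested, median −0.09, camera adjusted p = 0.423) had 1 member past the threshold, over all genes and adjusted over the list alone, FAS. Its list median was −0.01, −0.04 and −0.24 in siCFTR 1 to 3. With the length and GC trend removed its median log2 fold change was −0.02. Proliferation genes (36 tested, median 0.09, camera adjusted p = 0.227) and glycolysis and hypoxia targets (28 tested, median 0.01, camera adjusted p = 0.979) had none by either count. Without siNegControl 2 the proliferation list was called higher (median 0.14, camera adjusted p = 0.00734).

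Ribosomal protein genes, fixed as a sign of RNA quality, had a positive log2 fold change in 36 of 36 tested members (median 0.52, camera adjusted p = 9.76e-11), and nuclear oxidative phosphorylation genes in 28 of 28 (median 0.34, camera adjusted p = 9.78e-05). No member passed, over all genes or adjusted over the list alone, and the adjusted p = 0.934 and 0.959 with an estimated correlation. The ribosomal median against the control mean was 0.06 in siCFTR 1, 0.45 in siCFTR 2 and 1.05 in siCFTR 3, and the ribosomal median log2 fold change was 0.33 once the length and GC trend was removed. The oxidative phosphorylation median was −0.05 in siCFTR 1, 0.31 in siCFTR 2 and 0.87 in siCFTR 3, against −0.21 to 0.11 in the controls. That list's adjusted p was 0.0455 without siCFTR 3. With the length and GC trend removed its median log2 fold change was 0.25 (camera adjusted p = 0.00476 at the preset, 0.879 with an estimated correlation). Replication-dependent histone genes (6 tested, median 0.21, camera adjusted p = 0.276) had none past the threshold over all genes and 1 adjusted over the list alone, HIST1H2BC at 0.64 (SE 0.17). With the length and GC trend removed the histone median was −0.06 and HIST1H2BC was at 0.32. Of the 13 mitochondrially encoded genes none is listed. Other divisions of the 6 libraries into 3 and 3 called up to 10 of the 30 lists, against 8 for siCFTR and siNegControl.

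**Figure D2:**
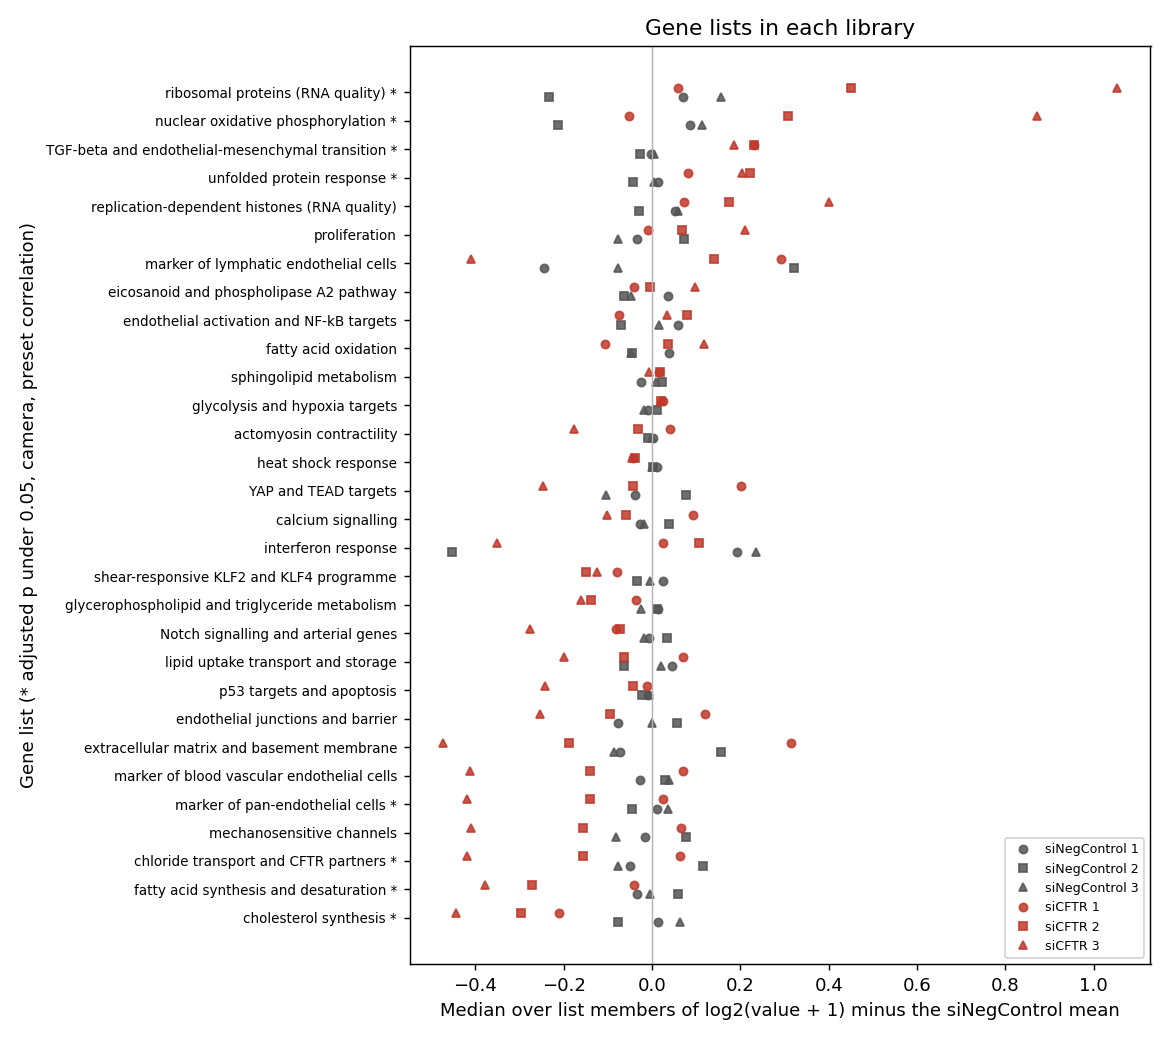
Median over the tested members of each of the 30 tested lists of log2(value + 1) minus the siNegControl mean, 1 point per library (grey siNegControl, red siCFTR), ordered by median log2 fold change. Asterisks mark the 8 lists past the threshold at the preset correlation; ribosomal proteins run from −0.23 in siNegControl 2 to 1.05 in siCFTR 3.

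The libraries differed along transcript length. The first principal component held 67.5% of the variance, with siCFTR 3 at one end (46.0) and siNegControl 2 at the other (−29.4). Across 12110 genes, which are not independent replicates, its loadings had a Spearman correlation of −0.59 and a Pearson correlation of −0.46 with log2 transcript length. The shift per doubling of length was −0.01, 0.12 and −0.004 log2 units in siNegControl 1 to 3 and 0.06, −0.02 and −0.14 in siCFTR 1 to 3. The median log2 fold change was 0.23 in the shortest sixth of transcripts and −0.11 in the longest.

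**Figure D3:**
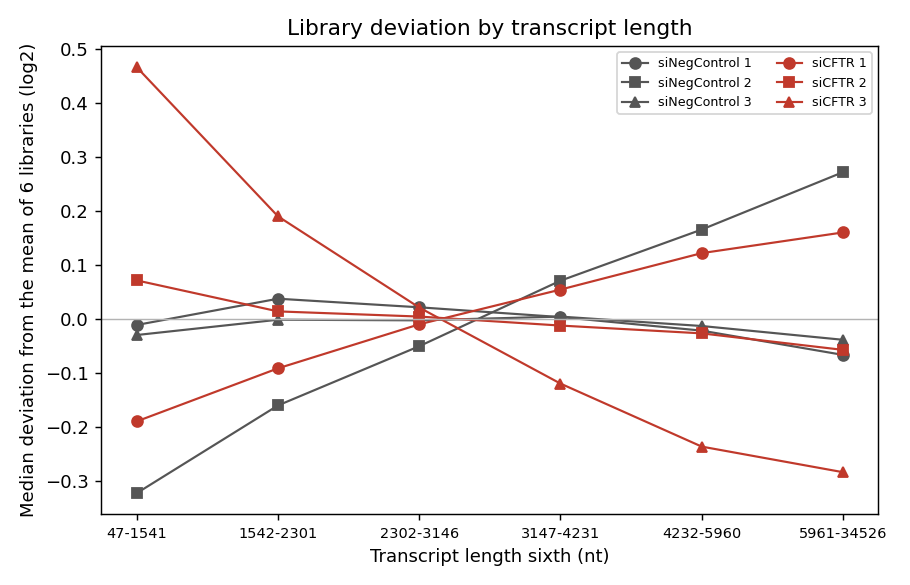
Median deviation (log2) of each library from the mean of the 6 libraries, for genes in 6 equal groups of transcript length (nt); grey lines are siNegControl and red lines siCFTR libraries. In the shortest group siCFTR 3 is at 0.47 and siNegControl 2 at −0.32, and siCFTR 1 and siCFTR 3 slope in opposite directions.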

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

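The settings that removed the length and GC trend, the 2 further pseudocounts and the unscaled values were chosen after the data were seen. Size factors by median ratio gave 53 genes (18 higher, 35 lower), upper-quartile factors 54 (19 and 35), a mean of at least 5 ppm 37, and pseudocounts of 0.25 and 5 gave 39 each. Library totals alone gave 38 (10 higher, 28 lower) and put the median log2 fold change of all genes at −0.12. Testing every gene above 0 gave 19 genes (7 higher, 12 lower). A fold minimum of 1.5 gave 0 by limma in both directions, with 96 at an unadjusted p under 0.05, and the values as deposited gave 1 (0 higher, 1 lower). With the length and GC trend removed there were 329 genes (150 higher, 179 lower), which included all 39. Leaving out 1 library gave from 0 to 151 genes, from 0 to 62 higher and from 0 to 89 lower: 0 without siNegControl 1, 2 or 3 or siCFTR 2, 127 without siCFTR 3 and 151 without siCFTR 1, the last 2 with all 39 genes included. Apart from the fewer libraries and the wider set tested, the cause was not tested.

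The correlations of same-numbered deviations were −0.44, 0.25 and 0.47, so the replicate numbers showed no consistent pairing. These deviations still held the length gradient, so they cannot settle whether the numbers pair the libraries. With the number as a replicate block, limma gave 0 genes in both directions (1406 at an unadjusted p under 0.05, smallest adjusted p = 0.0544), and with the length and GC trend also removed 114 (47 higher, 67 lower). Lists called numbered 8 under the block, 0 with an estimated correlation, 2 with fry, 6 with totals alone or without the length and GC trend, and from 6 to 9 without 1 library. No called gene or list changed sign, TRPV4 and PIEZO1 passed in no setting that tested them (TRPV4 falls under a mean of 5 ppm), and 32 values of genes and 43 of lists that were not called changed sign in some setting. The planned DESeq2, voom and unrounded-count fits were not run because they need counts. CFTR stayed at 0 with or without scaling. Depth is unknown, so no limit from depth can be given.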

Other observations

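The tests of the heptamer copies, of the NRF2 targets not yet looked at and of their sites, and of the lists across divisions of the libraries were set before their results were seen; the other tests here were chosen after. Genes outside the naming rule, picked after their values were seen, included GPAT3, which starts triglyceride synthesis and fell from 32.7 to 13.8 ppm (log2 fold change −1.19, SE 0.14, limma adjusted p = 0.0255), and the tight junction claudin CLDN1, which rose from 1.75 to 4.14 ppm (0.90, SE 0.12, limma adjusted p = 0.0361). Others passed once the length and GC trend was removed. Among these the hepatocyte growth factor receptor MET was at 1.40 (SE 0.12, limma adjusted p = 0.00310), the lipase inhibitor G0S2 at 1.25 (SE 0.23), the Wnt antagonist DKK1 at 0.86 (SE 0.13) and the pentraxin PTX3 at 0.77 (SE 0.13). The same setting put KLF2 at 0.88 and DICER1, which processes microRNA precursors, at −1.09 (SE 0.14, limma adjusted p = 0.0138); GPAT3 and DICER1, but also CLDN1, which rose, carry GATTCTG in the 3′ UTR.

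The siCFTR and siNegControl division gave 39 genes and the highest of the 9 others gave 0, so 1 of 10 divisions reached that count, but 10 are too few for a share under 0.05. For lists the real value was 8 and the highest other 10. As 3 of 10 divisions gave at least 8, the number of called lists did not set the real division apart from others. The division with 10 lists set siNegControl 1 and 3 and siCFTR 1 against the rest. All 39 called genes stayed past the threshold after each library's trend on transcript length and GC content was removed. That setting called 329 genes in all, so passing was easier and the count alone cannot decide on length bias. By log2 fold change, KDR went from −2.73 to −2.62 and H3F3AP4 from 1.37 to 1.08. LINC00537 had no matched transcript and was not corrected.

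Genes with GATTCTG in the 3′ UTR were lower in siCFTR. Each z came from limma t values after 3′ UTR length and A+T content, transcript length and GC content had been regressed out. Among 15810 heptamers and 11242 genes with a 3′ UTR of at least 50 nt, GATTCTG had the lowest z (−14.44, 1662 genes). Once the length and GC trend was removed its z was −14.73, and 1 shuffle of the genes reached −4.20. A search in 1 random set of genes gave the same heptamer, with a z of −9.62 in the remaining genes. A permutation of the regressed values there gave p = 1e-05 (one-sided, the smallest 100000 resamples can give). The permutation and the shuffle treat genes as independent, and all genes come from the same 6 libraries. Neither therefore measures the spread between libraries. The median log2 fold changes there, not regressed, were −0.12 with it and 0.01 without. The lowest z among 408 anagrams of the heptamer was −2.27. Composition had already been regressed out, so the anagrams cannot decide on it. A candidate explanation is pairing of a siRNA seed with 3′ UTRs. Medians were −0.18 for the octamer GATTCTGA (532 genes), −0.10 for the heptamer, −0.04 for ATTCTGA, −0.01 for the hexamer ATTCTG and 0.03 for none. With the length and GC trend removed they were −0.11, −0.04, −0.0005, 0.02 and 0.02, so the octamer and heptamer medians shrank and the hexamer was level with none. After 3′ UTR length and composition, genes with 2 or more copies (256) were lower than those with 1 (1406). The median difference was −0.05 (−0.0455, permutation p = 0.014, one-sided, again over genes and not libraries). Loss of CFTR as the cause stays open, since CFTR was listed at 0 in every library, and the labels give 1 CFTR siRNA product without its sequence.

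GACGTA is shared by most of the heptamers with the highest z in the same scan and was not tested in separate genes. It was held by 5 of the 12 called higher genes with a searched 3′ UTR, against 4.52% of those not called higher. The octamer, GATTCTG or ATTCTGA was held by 18 of the 24 called lower, against 25.8% of those not called lower. Both words were found in these same fold changes, so these counts are no separate evidence. The values give only the difference between 2 siRNAs, so a gene higher in siCFTR cannot be told from one lowered in siNegControl, whose siRNA sequence is not in the labels either. With the length and GC trend removed, each gene was also taken as its deviation from its mean over all libraries. The median deviation of octamer genes minus that of genes without a site was 0.09, 0.07 and 0.08 in the siNegControl libraries. In the siCFTR libraries it was −0.10, −0.07 and −0.07. Centring on that mean forces opposite signs in the groups, so these values cannot tell which siRNA moved the octamer genes. Without members holding the octamer, GATTCTG or ATTCTGA in the 3′ UTR, the cholesterol synthesis median was −0.29, against −0.26 with them. The fatty acid synthesis median was −0.24 without such members.

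Of 35 tested targets of NRF2, the regulator of antioxidant genes, 23 had a negative log2 fold change and 1 passed, SLC7A11. In 16 targets picked after some values were seen, among them TXNRD1, SLC7A11, HMOX1 and NQO1, the median log2 fold change was −0.40 (camera p = 0.00481 with an estimated correlation), with list medians of −0.27, −0.36 and −0.40 in siCFTR 1 to 3. In 19 tested targets whose values had not been looked at the median was −0.07 (−0.0736, 95% bootstrap interval over genes −0.37 to 0.11, camera p = 0.265 with an estimated correlation), with list medians of −0.32, −0.14 and 0.24 in siCFTR 1 to 3, which leaves lower NRF2 activity open. Seed sites may account for part, since TXNRD1 holds the heptamer and SLC7A11 the octamer. A set of 22 targets held neither the octamer, GATTCTG nor ATTCTGA in the 3′ UTR. Its median was −0.15 (−0.146, interval −0.37 to 0.09), which decides neither way. Targets with GATTCTG in the coding sequence were left out of the set. Holders of the hexamer ATTCTG (ME1, BLVRB and SLC48A1) were kept without that search. NFE2L2, which encodes NRF2, was at −0.25 (SE 0.13, limma adjusted p = 0.492). Its own 3′ UTR holds ATTCTGA, so seed sites and lower NRF2 activity may not be fully separate explanations. The median of that site class was −0.04, against 0.03 for none. Once the length and GC trend was removed the medians were −0.0005 and 0.02, so an effect of this site on NFE2L2 is uncertain.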
